A study of Homo sapiens with 6 samples.

How the data were processed

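RNA was measured in 6 libraries of MIA PaCa-2 cells, 3 with a non-silencing hairpin and 3 with a hairpin against CLPX. Per the labels' protocols, RNA was extracted with TRIzol, messenger RNA was selected by poly(A) and libraries were made with a TruSeq kit and random hexamer primers. Whether reads kept their strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart. The deposited table gives TPM per gene and library, computed by the authors, rounded to 2 decimals, and the columns have equal sums within rounding. The aligner, the counter, the genome build and the annotation are not given in the sources used here. The table has 61002 features, of which 40609 carry a gene symbol and 338 have names starting MSTRG, the prefix StringTie gives to assembled genes. The authors' 2 columns of group means equalled the means of the 3 libraries within 3.3e-05 and were used for nothing else. The gene length in bases, another column by the authors, was used to choose the transcript for GC content. It also served in the GC and length correction and in the comparisons with transcript length. TPM keeps no count, so library depth is unknown and no interval from counts can be given. Precision is known only from the spread of the 3 libraries in a group, which differed from one another in their values.

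Samples were grouped by their titles. Genes with at least 1 TPM in at least 3 of the 6 libraries were tested (13746 genes). Values were transformed as log2(TPM + 1), so a fold change is on that scale and understates the change of low genes. The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend, no covariates), two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. A count at least 2-fold adds an absolute log2 fold change of at least 1. In all sentences of the results, an adjusted p of a gene is limma's and one of a list or term is from limma's camera. CLPX was also tested with an exact two-sided permutation test over 20 assignments.

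Scaled values and counts are those after median-of-ratios scaling. The design, the alternatives, the rule for named genes and 51 gene lists were fixed before the data were examined. Of 993 planned list members, 990 were matched by symbol and 2 by an older or current symbol, after a member listed under both of its symbols was counted as 1. Lists covered ferroptosis, iron, haem, glutathione, mitochondrial complexes and maintenance, stress responses, lipids, proliferation, signalling, cell state and markers of other cell types. Each list with at least 3 tested members was tested with camera at a preset inter-gene correlation of 0.01, adjusted over 49 lists. Camera compares the list with all other tested genes. An estimated correlation and fry, which tests whether the members move one way on balance, were alternatives, and ranges over alternatives leave out fry. Terms of the annotation columns (GO and KEGG) with 10 to 500 tested members were tested in the same way. Named genes were a fixed set of 18 genes of the ClpX, haem and ferroptosis subject, the 12 largest rises and 12 largest falls among called genes with a symbol, a mean of at least 5 TPM in the higher group and no overlap of the groups, up to 4 members with the smallest adjusted p in each called list and 2 in each other list, and up to 3 members of each named term. RAC1 and HSPA1B are named beside their copies, and members of the families in the closing section, after their values were seen. Some genes that this rule selects are not reported here.

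The alternatives were a pseudocount of 0.1, no filter beyond a value above 0 in a library, a mean of at least 5 TPM, median-of-ratios scaling of the TPM columns, quantile normalization, removal of mitochondrially encoded genes, eBayes without trend, robust eBayes, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were a GC correction, a GC and length correction, and a fit on named genes with an Ensembl ID only. The GC correction fitted a loess curve (span 0.3) of each library's deviations from the gene means on transcript GC content. Gene means were those of log2(TPM + 1) over the libraries, and the fitted curve was removed. By construction this brings the typical fold change near 0 at each GC content. GC content and gene positions came from GENCODE 29 on GRCh38, which matched 58337 of the table's features and 13368 of the tested genes. GC content was that of the gene's GENCODE transcript nearest in length to the authors' gene length. Positions are those of that annotation, not of the authors' unknown build. Intervals of medians are 95% bootstrap intervals over genes from 1000 draws, and genes are not independent replicates. Figures were drawn with matplotlib 3.10.9.

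The fit was tested on simulated data with the 13746 genes and the spread of these libraries and 200 genes changed by known amounts. It recovered 48% of genes changed by −0.5, 56% changed by 0.5, 86% changed by 1 and 98% changed by 2 on the log2 scale, with 9 false calls. A planted list was called and 0 unchanged lists were, at the same adjusted p. Genes were simulated independently of one another, so these list results do not bear on lists whose members are correlated. On 13368 genes the GC correction took a planted trend of 0.5 log2 per 10 GC percent to −2e-04.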

Results

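The data are poly(A)-selected RNA sequencing profiles of MIA PaCa-2 cells, a line established from a human pancreatic ductal adenocarcinoma. Cells carried either a non-silencing short hairpin RNA (shNS, 3 libraries) or 1 hairpin against CLPX (shCLPX-1, 3 libraries). CLPX encodes the unfoldase of the mitochondrial protease ClpXP, and the series concerns loss of ClpX, ferroptosis and mitochondrial dysfunction. Values are the authors' TPM per gene, which keep no sequencing depth, so the depth behind each value is unknown. A mean of 14123 ± 59.6 genes (SD, n = 3) reached 1 TPM in shNS and 12443 ± 18.9 in shCLPX-1. The 100 most abundant genes held 42.5 ± 0.190% of the total in shNS and 49.4 ± 0.120% in shCLPX-1, and mitochondrially encoded genes held 4.66 ± 0.0630% and 5.88 ± 0.245%. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

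CLPX, the targeted gene, fell in shCLPX-1 from 41.5 ± 3.22 to 0.390 ± 0.0781 TPM (SD, n = 3 in each group), which left 0.94% of the shNS level and was lower in each of the 3 shCLPX-1 libraries than in any shNS library. Its log2 fold change was −4.93 (SE 0.090, limma adjusted p = 1.27e-07). An exact two-sided permutation test over the 20 assignments of the libraries gave p = 0.1, the smallest that 3 against 3 can give. The gene lies on chromosome 15 at 65148219 to 65185342, minus strand, in GENCODE 29 on GRCh38. CLPP, on chromosome 19 at 6361452 to 6368910, encodes the peptidase that degrades what ClpX unfolds, and it rose from 90.2 ± 13.6 to 131 ± 9.51 TPM (log2 fold change 0.55, limma adjusted p = 0.00325). With 1 hairpin, an effect of CLPX loss cannot be separated from an off-target effect of that hairpin.

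Among genes with a symbol, a mean of at least 5 TPM in the higher group and no overlap of the groups, the largest log2 rise was that of the pseudogene RAC1P2 (4.29), followed by HFM1 (3.86), FGF21 (3.79) and HSPA1A (3.45). The largest falls were those of CLPX (−4.93), HMMR (−4.58), which acts at the mitotic spindle, and KTN1 (−4.21). FGF21 and GDF15, secreted hormones induced by mitochondrial stress, rose 13.8-fold and 9.64-fold on the log2(TPM + 1) scale, GDF15 from 94.2 ± 6.85 to 915 ± 30.6 TPM. HSPA1A, the inducible heat shock chaperone HSP70, rose 10.9-fold, and HMOX1, which degrades haem and releases its iron, rose 5.01-fold from 16.8 ± 0.963 to 88.1 ± 2.07 TPM (SD, n = 3). DUSP2, FOS, PER1, UNC5B, GADD45B and S100P also rose, by 2.34 (S100P) to 3.26 (DUSP2) on the log2 scale. In that order these encode a MAP kinase phosphatase, an AP-1 subunit, a circadian repressor, a netrin receptor, a stress sensor and a calcium-binding protein. Besides CLPX, the 11 largest falls ran from −3.67 for CEBPZ to −4.58 for HMMR. They included SMC4 of condensin and NUF2 and CENPF of the kinetochore. TPR of the nuclear basket, the helicase RECQL, the septin SEPTIN7, ARHGAP5, which activates a GTPase, and the endoplasmic reticulum protein KTN1 were also among them. RAC1P2, a processed pseudogene of RAC1 on chromosome 4 at 46723830 to 46724408, rose from 0.507 ± 0.467 to 27.5 ± 1.81 TPM while RAC1 itself, from 229 ± 8.18 to 236 ± 6.44 TPM, did not pass as deposited (log2 fold change 0.05, limma adjusted p = 0.294). RAC1 was called higher after median-of-ratios scaling (0.61, adjusted p = 9.64e-06), GC correction (0.28, 2.54e-04) and GC and length correction (0.14, 0.0112), alternatives 9.64e-06 to 0.645. Reads of this pair cannot be assigned with certainty, and the source of the reads counted as RAC1P2 was not tested. HSPA1A has the near-identical copy HSPA1B, listed at 0 to 0.11 TPM, so its level too depends on how shared reads were assigned. HFM1, a meiotic helicase, was 17.1, 0.01 and 0.11 TPM in shNS and 32.5, 88.4 and 19.7 TPM in shCLPX-1 (limma adjusted p = 0.0171). Its call was lost without shNS replicate 2 (adjusted p = 0.0545), without shNS replicate 3 (0.0553), without shCLPX-1 replicate 2 (0.0571), with no filter on low values (0.0550) and with robust eBayes (0.0632), in a range over the alternatives of 4.00e-04 to 0.0632. With 1 library left out its log2 fold change ran from 3.14 (without shNS replicate 2) to 5.22 (without shNS replicate 1), so its rank among the rises is not fixed.

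**Figure D1:**
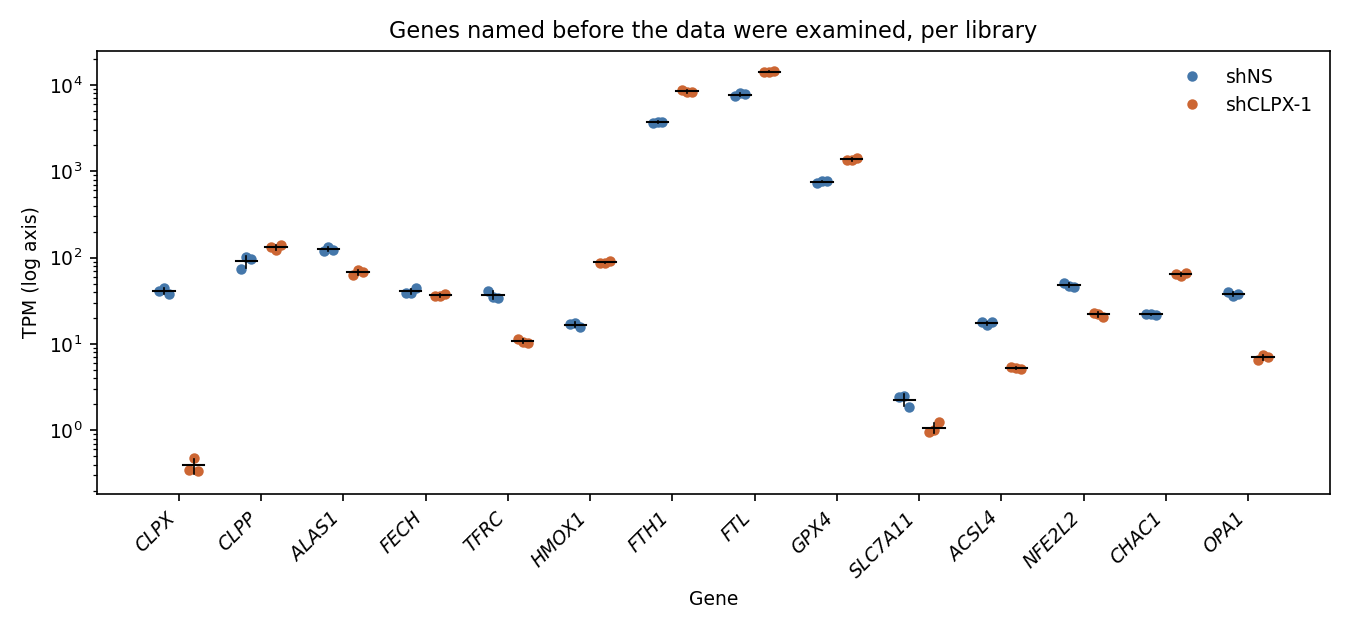
Levels of 14 genes named by the rule fixed before the data were examined, in TPM on a log axis, with a dot for each library (3 shNS, 3 shCLPX-1) and a bar for the group mean ± SD. CLPX falls from 41.5 to 0.390 TPM, and HMOX1 and CHAC1 are higher in all 3 shCLPX-1 libraries.

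Across all genes, falls outnumbered rises. Of 13746 genes tested with limma, 1628 rose and 8574 fell at an adjusted p under 0.05, with 139 rising and 3055 falling at least 2-fold, and the 2 groups did not overlap for 10550 genes (76.7%, against 10% by chance). The median log2 fold change of all tested genes was −0.47. Rescaling the TPM columns by median-of-ratios (the scaled values and counts) moved this median to −0.00456 and quantile normalization moved it to 0.0688. The calls then split into 4646 rises and 4588 falls, or 4867 rises and 4090 falls. The direction of many calls thus depends on the scaling. After median-of-ratios scaling 698 genes rose and 1380 fell at least 2-fold, and 898 of the 10202 calls were made in the opposite direction. Fold changes rose with the GC content of the transcripts across genes, which are not independent replicates (Spearman rho 0.631). The median log2 fold change was −1.34 in the 10% of genes with the lowest GC content and 0.0376 in the 10% with the highest. They went down with transcript length (rho −0.291, and −0.149 after GC correction), from a median of −0.18 in the 10% of genes with the shortest transcripts to −0.74 in the 10% with the longest. After a per-library correction for GC content, chosen after seeing the data, 4072 genes rose and 3777 fell, 418 and 496 of them at least 2-fold. By construction this correction sets the typical gene near 0 at each GC content, so it also undoes the shift of the median. Of the calls made before it, 5309 kept their direction and 1339 were called in the opposite direction. The largest falls named here had GC contents of 34.2% to 41.9%, and after the correction CLPX stood at −3.92, HMMR at −3.13, KTN1 at −2.88, SMC4 at −3.21, NUF2 at −2.88, CENPF at −3.02, ARHGAP5 at −2.23, SEPTIN7 at −2.52, TPR at −2.57, RECQL at −2.31 and CEBPZ at −2.47. Of 49 gene lists tested with camera, which compares a list with all other tested genes, 16 were placed above and 3 below. Only the list of ATF4 and integrated stress response targets was also called with an estimated inter-gene correlation, and all 19 were called in the same direction after GC correction. Adjusted over the list alone, the counts of members that rose and fell were those over all genes, except for 26 rises among ATF4 targets, 9 falls in haem synthesis and 3 rises in iron-sulphur cluster assembly. Where a list had none past the threshold in a direction, none had an unadjusted p under 0.05 in that direction either.

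**Figure D2:**
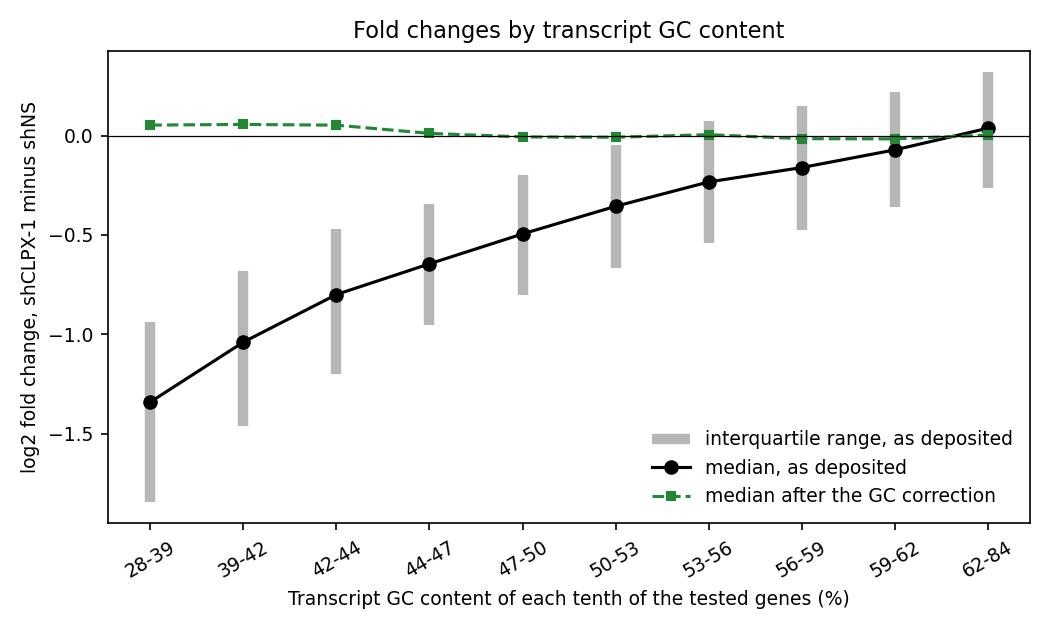
Median log2 fold change (shCLPX-1 minus shNS, log2(TPM + 1) scale) of 13368 tested genes in 10 bins of transcript GC content (percent), with bars for the interquartile range, and the bin medians after GC correction. The medians climb from −1.34 in the lowest bin to 0.0376 in the highest as deposited, while the corrected medians have no such slope by construction.

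**Figure D3:**
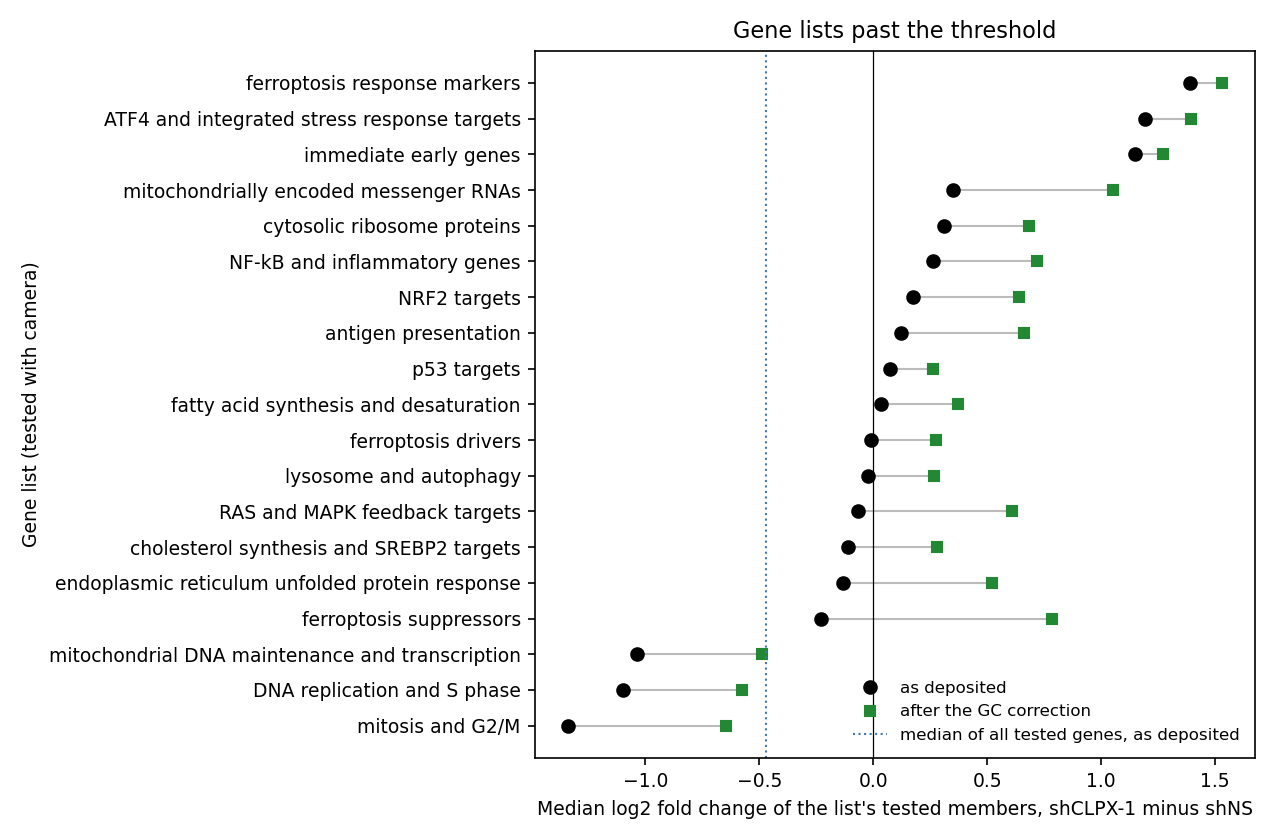
Median log2 fold change (shCLPX-1 minus shNS) of the tested members of the 19 gene lists called by camera, as deposited and after GC correction. ATF4 targets lie at 1.19 and 1.39, mitosis genes at −1.34 and −0.65.

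Genes of ferroptosis, the iron-dependent death by lipid peroxidation, moved in both directions. GPX4, the enzyme that reduces lipid peroxides, rose from 761 ± 16.2 to 1379.6 ± 55.9 TPM (log2 fold change 0.86, limma adjusted p = 1.5e-06), and the ferritin genes FTH1 and FTL, which store iron, rose by 1.19 and 0.88. HMOX1 (2.33) and CHAC1, which degrades glutathione (1.5), rose too. TFRC, the transferrin receptor, fell by 1.69 (GC-corrected −0.80) and ACSL4, which loads polyunsaturated fatty acids into lipids, fell by 1.56, from 17.5 ± 0.681 to 5.24 ± 0.120 TPM (GC-corrected −0.20, and −0.13, not called, after GC and length correction). NFE2L2, which encodes NRF2, fell by 1.09 as deposited and was 0.09 after GC correction. SLC7A11, the cystine importer, fell by 0.65, but stood at 0.84 after GC correction and was not called after median-of-ratios scaling (−0.31) or quantile normalization (−0.01). AIFM2 and DHODH, enzymes that keep coenzyme Q reduced, fell by 0.23 and 0.40 as deposited, but stood at 0.28 and 0.11 after median-of-ratios scaling. The AIFM2 call was lost without shCLPX-1 replicate 2 (limma adjusted p = 0.0554, alternatives 0.00128 to 0.471). NCOA4, the receptor for ferritin degradation, fell by 0.56 (GC-corrected 0.02, scaled −0.01). PTGS2, the cyclooxygenase often used as a ferroptosis marker, was too low to test, at 0.08 TPM in 1 shNS library and listed at 0 in the others.

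Among ferroptosis response markers, 7 of 11 tested members rose and 3 fell (scaled 8 and 2, GC-corrected 10 and 1), and the list lay above other genes (camera adjusted p = 1.93e-06, adjusted p = 0.0916 with an estimated correlation, alternatives 1.15e-06 to 0.0916). Its leading members besides FTH1 and HMOX1 were DDIT4, an mTORC1 inhibitor (1.40), and ASNS, asparagine synthetase (1.59, GC-corrected 2.23). CHAC1, SLC7A11, ATF3, DDIT4, TRIB3, ASNS and VLDLR of this list are also on the list of ATF4 and integrated stress response targets. The placements of these lists are therefore not separate results. For ferroptosis suppressors, 7 of 19 tested members rose and 10 fell (scaled 10 and 2, GC-corrected 12 and 0), led by SLC3A2, the partner chain of SLC7A11 (1.34). This list was placed above other genes (camera adjusted p = 0.00310, adjusted p = 0.141 with an estimated correlation, alternatives 2.48e-05 to 0.141) although its median was −0.23 and its mean 0.000271, and the call was lost with no filter on low values (0.0501). Of ferroptosis drivers, 6 of 18 tested members rose and 8 fell (scaled 12 and 4, GC-corrected 10 and 3), with a rise of SAT1, a polyamine acetylating enzyme (1.25, GC-corrected 2.03). The drivers were placed above other genes (camera adjusted p = 0.0436, adjusted p = 0.195 with an estimated correlation, alternatives 0.0250 to 0.293) although their median was −0.01 and their mean −0.10. That call was lost without shNS replicate 1 (adjusted p = 0.0639), without shCLPX-1 replicate 2 (0.0605), and with median-of-ratios scaling (0.0551), quantile normalization (0.293) or either other filter (0.0969 and 0.189). NRF2 targets of the antioxidant programme were placed higher (camera adjusted p = 1.41e-04, adjusted p = 0.1 with an estimated correlation, alternatives 1.98e-06 to 0.1). Of these targets, 10 of 19 tested members rose and 7 fell (scaled 14 and 2, GC-corrected 15 and 0). OSGIN1 (1.5) rose, while GCLM, the modifier subunit for glutathione synthesis, fell by 1.42 (GC-corrected −0.04, not called). In glutathione synthesis and use, 5 of 17 tested members rose and 7 fell (scaled 11 and 4, GC-corrected 12 and 2, camera adjusted p = 0.0559), and the list was called without shNS replicate 2 (0.0475) or shCLPX-1 replicate 3 (0.0426) and after GC correction (0.00365), alternatives 0.00365 to 0.456. Of antioxidant enzymes, 7 of 19 tested members rose and 10 fell (scaled 12 and 4, GC-corrected 15 and 3, camera adjusted p = 0.158). They included the mitochondrial peroxiredoxin PRDX3 (−1.30, GC-corrected −0.21) and the stress-induced sestrin SESN2 (1.35). The antioxidant list was placed above other genes after scaling (adjusted p = 0.0430) and GC correction (8.43e-04, alternatives 8.43e-04 to 0.911).

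In haem synthesis, 2 of 11 tested members rose and 8 fell (scaled 6 and 3, GC-corrected 3 and 5, camera adjusted p = 0.921). ALAS1, the rate-limiting enzyme whose activation ClpX assists, fell from 125 ± 6.27 to 67.6 ± 4.71 TPM (log2 fold change −0.88, GC-corrected −0.51), and CPOX, a later enzyme, stood at −1.09 (GC-corrected −0.50). FECH, which inserts iron into the ring, had a log2 fold change of −0.15 that did not pass (limma adjusted p = 0.0577). It was called lower without shNS replicate 1 (adjusted p = 0.0482, alternatives 1.21e-04 to 0.168), but stood at 0.40 after median-of-ratios scaling and 0.59 after GC correction. Leaving out 1 library at a time moved it between −0.18 and −0.09. Of genes for iron uptake, storage and export, 4 of 15 tested members rose and 10 fell (scaled 7 and 3, GC-corrected 6 and 4, camera adjusted p = 0.294), led by HMOX1 and FTH1. For iron-sulphur cluster assembly, 2 of 15 tested members rose and 11 fell (scaled 7 and 2, GC-corrected 10 and 2, camera adjusted p = 0.994), and the list was placed above other genes after GC correction (0.00929, alternatives 0.00929 to 0.997). BOLA3 (−0.70, GC-corrected −0.29) and the chaperone HSPA9 (−0.37, GC-corrected 0.56), 0.19 after median-of-ratios scaling, were its leading members.

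Of mitochondrially encoded messenger RNAs, 9 of 13 tested members rose and 2 fell (scaled 13 and 0, GC-corrected 13 and 0), and the list lay above other genes (camera adjusted p = 9.68e-08, adjusted p = 0.209 with an estimated correlation, alternatives 1.17e-08 to 0.360), a call that quantile normalization ended (0.360). MT-CO2 rose from 5766 ± 237 to 9188 ± 431 TPM (log2 fold change 0.67, GC-corrected 1.28), and MT-ND3 (0.59, GC-corrected 1.73), MT-ND2 (0.39, GC-corrected 1.25) and MT-CO3 (0.39, GC-corrected 0.98) rose, though MT-CO3 was not called after quantile normalization (0.05). Nuclear copies of these sequences can share their reads. The 13 messengers, at 39.6% to 47.7% GC, had a median log2 fold change of 0.35 against −0.78 for 4149 nuclear genes in that range. Genes of mitochondrial DNA maintenance and transcription went down, as 14 of 16 tested members fell and none rose (scaled 3 and 9, GC-corrected 3 and 11). Their median was −1.04, or −0.49 after GC correction (camera adjusted p = 0.0472, adjusted p = 0.234 with an estimated correlation, alternatives 4.54e-04 to 0.234). TFAM, which packages mitochondrial DNA, fell from 33.9 ± 4.72 to 7.29 ± 0.521 TPM (log2 fold change −2.07, GC-corrected −0.76), and the transcription and RNA stability factors MTERF3 (−2.03, GC-corrected −0.99), LRPPRC (−1.72, GC-corrected −0.81) and SLIRP (−0.95, GC-corrected −0.78) fell too. The list's call was lost without shCLPX-1 replicate 1 (adjusted p = 0.0606), without shCLPX-1 replicate 2 (0.0585), with median-of-ratios scaling (0.0832), at a mean of at least 5 TPM (0.0745), without mitochondrially encoded genes (0.0507) and with named genes only (0.0560). OPA1, the fusion factor of the inner membrane, fell from 37.9 ± 2.28 to 6.96 ± 0.406 TPM (log2 fold change −2.29, GC-corrected −0.97).

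Nuclear lists of the respiratory chain were not placed apart from other genes as deposited. Of complex I subunits, 10 of 37 tested members rose and 23 fell (scaled 24 and 6, GC-corrected 24 and 5, camera adjusted p = 0.261). Members included NDUFB3 (−1.97, GC-corrected −0.88) and NDUFS4 (−1.64, GC-corrected −0.77). Among complexes II and III, 2 of 14 tested members rose and 10 fell (scaled 8 and 4, GC-corrected 9 and 1, camera adjusted p = 0.921). Members included UQCRB (−1.31, GC-corrected 0.03) and SDHD (−1.03, GC-corrected 0.02). Complex IV and its assembly factors had a similar balance, where 4 of 18 tested members rose and 9 fell (scaled 10 and 7, GC-corrected 11 and 4, camera adjusted p = 0.524). Members included COX7B (−1.59, GC-corrected −0.58) and SCO1 (−1.09, GC-corrected −0.39). In the ATP synthase, 3 of 16 tested members rose and 13 fell (scaled 11 and 2, GC-corrected 9 and 2, camera adjusted p = 0.760), and ATP5PB stood at −1.05 (GC-corrected −0.20) and ATP5F1E at −0.98 (GC-corrected 0.30). In the citric acid cycle, 2 of 22 tested members rose and 16 fell (scaled 13 and 5, GC-corrected 11 and 4, camera adjusted p = 0.520), and SUCLA2 (−2.23, GC-corrected −1.0) and DLD (−1.79, GC-corrected −0.57), subunits of its dehydrogenase and ligase steps, fell. With no filter on low values that list was placed below other genes (0.0488). After GC correction, which moved most of these members up, the lists for complex I, complexes II and III, complex IV, ATP synthase and the citric acid cycle were all placed above other genes (adjusted p = 0.00300, 0.0124, 0.0340, 0.0157 and 0.0340). All 5 calls were lost after GC and length correction (0.171, 0.176, 0.291, 0.322 and 0.0609). Median-of-ratios scaling placed complex I (0.00135) and ATP synthase (0.0320) above other genes, but quantile normalization placed ATP synthase below them (0.0336). Over all alternatives the adjusted p of these lists ranged from 0.00135 to 0.826, 0.0124 to 0.962, 0.0340 to 0.979, 0.0157 to 0.877 and 0.0340 to 0.682. Of mitochondrial ribosome proteins, 6 of 35 tested members rose and 21 fell (scaled 20 and 11, GC-corrected 15 and 12, camera adjusted p = 0.932). Members included MRPL19 (−1.59, GC-corrected −0.28) and MRPL3 (−0.83, GC-corrected −0.20). Among partners of ClpX and other mitochondrial proteases, 3 of 13 tested members rose and 8 fell (scaled 6 and 3, GC-corrected 5 and 4, camera adjusted p = 0.994), and the inner-membrane proteases YME1L1 and SPG7 stood at −1.24 and −0.97 (GC-corrected −0.22 and −0.86). Of mitochondrial chaperones and the mitochondrial unfolded protein response, 6 of 14 tested members rose and 8 fell (scaled 8 and 4, GC-corrected 7 and 1, camera adjusted p = 0.158). HSPE1, the co-chaperonin, fell by 2.09 (GC-corrected −1.21), and DDIT3, which encodes the stress factor CHOP, rose by 1.49. The chaperone list was placed above other genes after GC correction (0.0170, alternatives 0.0170 to 0.963). For fusion, fission and mitophagy, 3 of 15 tested members rose and 10 fell (scaled 9 and 3, GC-corrected 8 and 6, camera adjusted p = 0.824), among them OPA1 and the fission GTPase DNM1L (−1.66, GC-corrected −0.60). Of fatty acid oxidation, 3 of 17 tested members rose and 11 fell (scaled 11 and 5, GC-corrected 10 and 4, camera adjusted p = 0.950), where ACADM fell by 2.02 (GC-corrected −0.65) and ECI1 rose by 0.89 (GC-corrected 0.87).

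Targets of ATF4 and the integrated stress response, the programme by which cells answer amino acid and mitochondrial stress, rose together. Of these, 25 of 29 tested members rose and 1 fell (scaled 27 and 0, GC-corrected 29 and 0), with a median log2 fold change of 1.19, or 1.39 after GC correction. GDF15 led them, and PPP1R15A, which reverses the translational block of this response, rose from 51.3 ± 1.30 to 205 ± 8.31 TPM (SD, n = 3). DDIT3 rose by 1.49 and DDIT4 by 1.40. The list lay above other genes (camera adjusted p = 3.51e-28, adjusted p = 0.0151 with an estimated correlation, alternatives 4.33e-35 to 0.0151). In the unfolded protein response of the endoplasmic reticulum, HSPA5, the chaperone BiP, rose from 379.6 ± 12.4 to 1778 ± 27.6 TPM (log2 fold change 2.23, GC-corrected 2.84), HERPUD1 (1.91, GC-corrected 2.42) and XBP1 (0.69, GC-corrected 1.12) rose and HSP90B1 fell (−1.24, GC-corrected −0.33). Overall in that list 7 of 19 tested members rose and 9 fell (scaled 13 and 3, GC-corrected 15 and 2), and its camera placement above other genes (camera adjusted p = 0.01, adjusted p = 0.158 with an estimated correlation, alternatives 2.30e-04 to 0.158) went with a median of −0.13 and a mean of 0.10. It was lost with quantile normalization (0.0873). Immediate early genes, induced within minutes of a stimulus, rose, as 14 of 16 tested members rose and none fell (scaled 16 and 0, GC-corrected 16 and 0, camera adjusted p = 4.38e-17, adjusted p = 0.0916 with an estimated correlation, alternatives 6.45e-20 to 0.0916). FOS rose from 7.38 ± 1.01 to 69.4 ± 2.40 TPM, and the phosphatase and AP-1 genes DUSP1 (2.09, GC-corrected 2.31), JUNB (1.58, GC-corrected 1.55) and JUN (0.97, GC-corrected 1.13) rose as well. In the heat shock response, 3 of 15 tested members rose and 10 fell (scaled 7 and 7, GC-corrected 4 and 7, camera adjusted p = 0.921), so that HSPA1A (3.45) and DNAJB1 (1.45) rose while HSP90AA1 fell by 2.95 (GC-corrected −2.28). Quantile normalization placed the heat shock list below other genes (adjusted p = 0.0336, alternatives 0.0336 to 0.993).

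Of NF-kB and inflammatory genes, 8 of 16 tested members rose and 3 fell (scaled 13 and 2, GC-corrected 12 and 0, camera adjusted p = 2.96e-05, adjusted p = 0.141 with an estimated correlation, alternatives 1.5e-05 to 0.141). RELB, LIF and NFKBIA, an NF-kB subunit, a cytokine and an inhibitor of the pathway, rose by 1.33, 1.14 and 0.60, while CXCL8 fell by 0.73 as deposited and stood at 0.86 after GC correction. In RAS and MAPK feedback targets, 8 of 20 tested members rose and 9 fell (scaled 13 and 4, GC-corrected 13 and 3), with rises of FOSL1 (1.20, GC-corrected 1.27), EGR1 (1.20, GC-corrected 1.40), IER3 (1.01, GC-corrected 1.13) and EPHA2 (0.56, GC-corrected 0.63). That list's camera call (camera adjusted p = 0.0126, adjusted p = 0.214 with an estimated correlation, alternatives 0.00215 to 0.214) went with a median of −0.07 and a mean of −0.06. It was lost with quantile normalization (0.0910) and with no filter (0.0784). Among p53 targets, 8 of 20 tested members rose and 8 fell (scaled 12 and 7, GC-corrected 12 and 3), with a median of 0.07 and a mean of −0.05 (camera adjusted p = 8.60e-04, adjusted p = 0.195 with an estimated correlation, alternatives 7.26e-04 to 0.195). The p53 call was lost with median-of-ratios scaling (0.0832) and quantile normalization (0.0910). GDF15, SESN2 and the death gene BBC3 (1.49) rose, and CCNG1 fell (−1.18, GC-corrected 0.14). Of cell death regulators, 5 of 19 tested members rose and 10 fell (scaled 10 and 6, GC-corrected 12 and 4, camera adjusted p = 0.203), with BBC3 up and the apoptosis inhibitor BIRC2 down (−2.11, GC-corrected −0.78). GC correction placed the cell death list above other genes (0.0300, alternatives 0.0300 to 0.490). For YAP and TEAD targets, 3 of 15 tested members rose and 7 fell (scaled 7 and 3, GC-corrected 7 and 3, camera adjusted p = 0.414). Members included TEAD1 (−1.55, GC-corrected −0.53) and CRIM1 (−1.30, GC-corrected −0.75). Type I interferon response genes were not placed apart (camera adjusted p = 0.294), as 6 of 26 tested members rose and 14 fell (scaled 10 and 10, GC-corrected 10 and 10), with falls of IFIT3 (−1.74, GC-corrected −0.99) and IFIT2 (−1.60, GC-corrected −0.73). Antigen presentation genes lay above other genes (camera adjusted p = 8.54e-04, adjusted p = 0.133 with an estimated correlation, alternatives 3.20e-04 to 0.133), and 6 of 14 tested members rose and 3 fell (scaled 10 and 1, GC-corrected 9 and 0). The HLA genes HLA-B (0.65, GC-corrected 0.76), HLA-C (0.64, GC-corrected 0.71) and HLA-E (0.53, GC-corrected 0.75) rose, with similar sequences that can share reads.

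Genes of cell division went down. All 28 tested genes of mitosis and G2/M fell as deposited, with a median log2 fold change of −1.34 (camera adjusted p = 6.05e-07, adjusted p = 0.158 with an estimated correlation, alternatives 1.55e-14 to 0.158). TOP2A, the topoisomerase of dividing cells, fell from 175 ± 10.0 to 37.9 ± 0.712 TPM (SD, n = 3, GC-corrected log2 fold change −0.93), HMMR from 99.7 ± 4.14 to 3.22 ± 0.492 TPM, the spindle checkpoint kinase TTK by 3.57 (GC-corrected −2.14) and the cytokinesis protein ANLN by 2.69 (GC-corrected −1.54). Under median-of-ratios scaling 3 members rose and 22 fell, and after GC correction 26 fell, none rose, and the median was −0.65. The members' median GC content was 44.1%. Among genes of DNA replication and S phase, 1 of 27 tested members rose and 26 fell (scaled 2 and 23, GC-corrected 1 and 21), with a median of −1.10, or −0.58 after GC correction (camera adjusted p = 1.33e-04, adjusted p = 0.158 with an estimated correlation, alternatives 2.77e-10 to 0.158). PCNA, the polymerase clamp, fell from 149 ± 6.03 to 47.8 ± 0.646 TPM (log2 fold change −1.62, GC-corrected −0.95), and the helicase and clamp loader subunits MCM3 (−1.57, GC-corrected −1.22), MCM7 (−1.10, GC-corrected −0.90) and RFC4 (−1.53, GC-corrected −0.79) fell. Of MYC targets, 4 of 23 tested members rose and 14 fell (scaled 13 and 7, GC-corrected 7 and 12, camera adjusted p = 0.932). Members included the nucleolar proteins NPM1 (−1.37, GC-corrected −0.30) and NCL (−1.09, GC-corrected −0.98). Cytosolic ribosome proteins went the other way, as 22 of 32 tested members rose and 8 fell (scaled 28 and 3, GC-corrected 29 and 3, camera adjusted p = 3.76e-12, adjusted p = 0.1 with an estimated correlation, alternatives 8.50e-13 to 0.799), a call that quantile normalization ended (0.799). The ribosomal genes RPL8 (0.72, GC-corrected 0.75), RPL18 (0.69, GC-corrected 0.82) and RPS2 (0.67, GC-corrected 0.91) rose and RPS24 fell (−1.60, GC-corrected −1.21), each with processed pseudogenes that can share reads. In replication-dependent histones, whose messengers mostly lack poly(A) tails, 2 of 14 tested members rose and 5 fell (scaled 6 and 3, GC-corrected 4 and 1, camera adjusted p = 0.0881), with H2AC20 at 1.13 and H2BC12 at −0.87. That list was called without shNS replicate 2 (adjusted p = 0.0458) and without shCLPX-1 replicate 3 (0.0307), alternatives 0.0307 to 0.965.

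Lipid, lysosomal and glycolytic lists had members in both directions. For lysosome and autophagy, 8 of 24 tested members rose and 11 fell (scaled 18 and 3, GC-corrected 15 and 2), and the list was placed above other genes with a median of −0.02 and a mean of 0.02 (camera adjusted p = 0.00310, adjusted p = 0.195 with an estimated correlation, alternatives 0.00131 to 0.195), a call that quantile normalization ended (0.0518). MAP1LC3B, the autophagosome protein LC3B, rose from 115 ± 3.60 to 303 ± 5.83 TPM, its cargo receptor SQSTM1 rose by 0.92, and ATG5 (−1.47, GC-corrected −0.20) fell as deposited, without a call after GC correction. Of fatty acid synthesis and desaturation, 4 of 13 tested members rose and 3 fell (scaled 10 and 1, GC-corrected 7 and 1), with a median of 0.03 and a mean of −0.08 (camera adjusted p = 0.0213, adjusted p = 0.188 with an estimated correlation, alternatives 0.00407 to 0.204). Its call was lost without shCLPX-1 replicate 2 (adjusted p = 0.0623), with quantile normalization (0.204) and with either other filter (0.0501 and 0.0577). SREBF1, a lipogenic transcription factor, and MID1IP1 rose by 0.52 and 0.80, while ACSL3 fell (−1.29, GC-corrected 0.04). ACLY fell (−0.44, but 0.12 after median-of-ratios scaling and −0.05, not called, after GC and length correction). In cholesterol synthesis, 7 of 21 tested members rose and 10 fell (scaled 12 and 4, GC-corrected 12 and 3), with a median of −0.11, a mean of −0.17 and a camera placement above other genes (camera adjusted p = 0.0436, adjusted p = 0.209 with an estimated correlation, alternatives 0.00929 to 0.209). That placement was lost without shNS replicate 1 (adjusted p = 0.0555), without shCLPX-1 replicate 2 (0.0605), with quantile normalization (0.0723) and with either other filter (0.163 and 0.0888). INSIG1 and DHCR7 rose by 0.79 and 0.66 (GC-corrected 1.41 and 0.78), and HSD17B7 fell by 1.00 (GC-corrected −0.43). Among glycolysis and hypoxia genes, 6 of 26 tested members rose and 13 fell (scaled 18 and 4, GC-corrected 14 and 6, camera adjusted p = 0.158), including the glycolytic mutase PGAM1 (−0.95, GC-corrected −0.65) and ANKRD37, a hypoxia target (−1.68, GC-corrected −1.02). The glycolysis list was placed above other genes after scaling (adjusted p = 0.00822, alternatives 0.00822 to 0.911).

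Lists of cell state and of other cell types were not placed apart from other genes. Of epithelial genes, 2 of 8 tested members rose and 4 fell (scaled 5 and 1, GC-corrected 4 and 3, camera adjusted p = 0.414), with the keratins KRT19 at −1.04 and KRT8 at −0.60 (−0.04 after median-of-ratios scaling). Of mesenchymal genes, 3 of 12 tested members rose and 7 fell (scaled 7 and 3, GC-corrected 4 and 6, camera adjusted p = 0.524), with falls of ZEB1, a transcription factor of that state (−2.50, GC-corrected −1.26), and TGFBI (−0.98, GC-corrected −0.72). Among integrins and other matrix receptors, 3 of 16 tested members rose and 8 fell (scaled 9 and 4, GC-corrected 6 and 5, camera adjusted p = 0.520), including ITGA6 (−1.52, GC-corrected −0.66) and ITGB1 (−0.69, GC-corrected 0.47). In the fibroblast and stellate list, 4 of 5 tested members fell and none rose (scaled 1 and 3, GC-corrected 1 and 4, camera adjusted p = 0.520), with RGS5 (−2.04, GC-corrected −1.26) and COL3A1 (−0.99, GC-corrected −0.67), COL3A1 without a call after quantile normalization (−0.29). For islet and neuroendocrine markers, 2 of 3 tested members fell and none rose (scaled 1 and 1, GC-corrected 0 and 1, camera adjusted p = 0.921), namely SCG2 (−1.37, GC-corrected −0.52) and PAX6 (−0.54, scaled −0.04, GC-corrected 0.04). Of haematopoietic markers, 1 of 4 tested members rose and 2 fell (scaled 3 and 0, GC-corrected 2 and 2, camera adjusted p = 0.307). CD14 stood at 0.80 and CD79A at −0.81, whose call was lost without shCLPX-1 replicate 1 (limma adjusted p = 0.0547) and without shCLPX-1 replicate 3 (0.0534), with no filter (0.0554), after scaling (−0.53, 0.0803) and after quantile normalization (−0.16, 0.574), alternatives 0.0125 to 0.574. With 1 library left out CD79A ran from −0.96 (without shNS replicate 1) to −0.53 (without shNS replicate 3). Among erythroid markers, 1 of 3 tested members fell and none rose (scaled 0 and 0, GC-corrected 0 and 1, camera adjusted p = 0.931). This was HBA2 (24.4 ± 13.2 to 9.86 ± 2.02 TPM, log2 fold change −1.11), a near copy of HBA1. Its call was lost without shCLPX-1 replicate 2 (limma adjusted p = 0.0725), with no filter (0.0678), after scaling (−0.59, 0.175) and after quantile normalization (−0.55, 0.240), alternatives 0.00405 to 0.240. With 1 library left out HBA2 ran from −1.46 (without shNS replicate 1) to −0.72 (without shNS replicate 3). For markers of embryonic kidney cells, which are often used to package hairpin viruses, 2 of 3 tested members fell and none rose (scaled 2 and 1, GC-corrected 0 and 2, camera adjusted p = 0.994). These were PAX2 (−0.69, not called after quantile normalization at −0.06) and GAL (−0.31, 0.25 after median-of-ratios scaling, not called after quantile normalization at −0.12). None of the 18 acinar markers and 2 of the 11 endothelial markers were high enough to test, so neither list was tested.

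Among 2764 annotation terms in the authors' table, camera placed 65 above and 33 below all other genes. With an estimated correlation camera called 0, and 140 had an unadjusted p under 0.05. After GC correction 71 terms were placed above and 66 below, 55 of them in the same direction as before. For protein targeting to membranes by the signal recognition particle, 49 of 92 tested members rose and 32 fell (scaled 70 and 10, GC-corrected 78 and 9, adjusted p = 4.85e-11). Its members RPS24 (−1.60) and SRP9 (−1.82, GC-corrected −0.35) fell, and RPL36 rose (0.74). The term thus includes ribosomal proteins, whose list lost its call with quantile normalization (camera adjusted p = 0.799), an alternative not run on terms. In the response to cAMP, 12 of 20 tested members rose and 5 fell (scaled 14 and 4, GC-corrected 13 and 4, adjusted p = 6.07e-06), with PER1, DUSP1 and JUNB at 2.91, 2.09 and 1.58. Of cytokine and receptor interaction genes, 32 of 85 tested members rose and 31 fell (scaled 40 and 22, GC-corrected 43 and 14, adjusted p = 2.08e-04), a call lost with median-of-ratios scaling (0.0665). GDF15 rose by 3.27, the receptor TNFRSF12A by 1.63 and the cytokine IL32 by 1.58. The KEGG ferroptosis pathway was placed above other genes, where 13 of 29 tested members rose and 14 fell (scaled 19 and 5, GC-corrected 19 and 4, adjusted p = 0.00374), with HMOX1, SLC3A2 and SAT1 at 2.33, 1.34 and 1.25. At the centromeric region of chromosomes, none of 54 tested members rose and 49 fell (scaled 6 and 34, GC-corrected 5 and 41, adjusted p = 1.84e-04), with NUF2 (−4.15, GC-corrected −2.88), CBX3 (−2.73, GC-corrected −1.53) and SMC3 (−3.19, GC-corrected −1.93). Among proteins that bind replication origins, none of 21 tested members rose and 21 fell (scaled 1 and 18, GC-corrected 1 and 16, adjusted p = 0.00546), including MCM3 (−1.57, GC-corrected −1.22), MCM7 (−1.10, GC-corrected −0.90) and ORC6 (−1.80, GC-corrected −1.18). For genes that the authors' annotation lists as structural proteins of the nuclear pore, none of 23 tested members rose and 22 fell (scaled 1 and 15, GC-corrected 0 and 18, adjusted p = 0.0102). TPR, UPF3B and NUP155 stood at −3.71, −2.22 and −1.33 (GC-corrected −2.57, −1.26 and −0.36). Among DNA repair genes, 10 of 210 tested members rose and 165 fell (scaled 55 and 110, GC-corrected 39 and 105, adjusted p = 0.0251), with RAD51AP1 (−2.90, GC-corrected −1.44) falling and GADD45A rising (1.84).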

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

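The GC correction, the GC and length correction and the fit on named genes with an Ensembl ID only were chosen after the results were seen. CLPX fell and passed under each alternative, from −6.42 to −3.85. Leaving out each library in turn gave 1457 to 1588 rises and 8074 to 8313 falls, 134 to 152 and 2967 to 3076 at least 2-fold, CLPX at −4.99 to −4.88, 13 to 18 lists up and 2 to 3 down, and 62 to 68 terms up and 33 to 40 down. With the replicate number as a block, 1610 genes rose and 8455 fell, 147 and 3061 at least 2-fold, 15 lists were called up and 2 down, 62 terms up and 31 down, and CLPX stood at −4.93. It called 9856 of the 10202 genes in the same direction and 0 in the opposite direction. The cholesterol list (0.0528) and the mitochondrial DNA list (0.0575) were not called and FECH was (−0.15), with no other call of a list or named gene changed. Deviations of libraries with the same number correlated at 0.00565, −0.00714 and 0.0770, and not every library correlated best with its own number. No pairing by number was thus detected, though weak correlations cannot show that the libraries were not made in pairs. The labels do not say whether the numbers pair them.

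Median-of-ratios scaling gave 4646 rises and 4588 falls, 698 and 1380 at least 2-fold, and 55 terms down. Of the 10202 calls, 6216 kept their direction and 898 were called in the opposite direction. Quantile normalization gave 4867 rises and 4090 falls, 619 and 1062 at least 2-fold, with 7 lists up and 5 down. Both set the typical gene near 0 by construction, as the GC correction does at each GC content. The GC correction gave 4072 rises and 3777 falls, 418 and 496 at least 2-fold, 26 lists up and 66 terms down. GC and length correction gave 4064 and 3687, 393 and 493 at least 2-fold. A mean of at least 5 TPM tested fewer genes (9352), and 1965 fell at least 2-fold. With an estimated correlation 1 list was called up and 0 down, and 0 terms up and 0 down. Fry called 30 lists down.

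Some directions turned. Fry, which does not compare a list with other genes, gave a downward direction for antioxidant enzymes (1.63e-04), cell death regulators (0.00908), cholesterol synthesis and SREBP2 targets (0.0154), ClpXP partners and mitochondrial proteases (7.20e-06), complex I (3.15e-04), complex IV (2.53e-04), embryonic kidney line markers (0.00260), epithelial genes (3.08e-04), fatty acid oxidation (7.51e-05), fatty acid synthesis and desaturation (0.730), glutathione synthesis and use (0.00232), glycolysis and hypoxia response (0.00528), matrix receptors and integrins (3.15e-04), mesenchymal genes (2.70e-04), mitochondrial chaperones (0.00171), mitochondrial fusion and fission (1.35e-04), mitochondrial ribosome proteins (7.20e-06), type I interferon response (2.75e-06) and YAP and TEAD targets (7.36e-04). Upward after median-of-ratios scaling was ATP synthase (0.0320), and after GC correction ATP synthase (0.0157), citric acid cycle (0.0340), complexes II and III (0.0124) and iron-sulphur cluster assembly (0.00929), with iron-sulphur cluster assembly (0.0191) after GC and length correction. Of genes that stood lower as deposited, median-of-ratios scaling gave log2 fold changes of ACLY 0.12, AIFM2 0.28, DHODH 0.11, FECH 0.40, GAL 0.25 and HSPA9 0.19, quantile normalization AIFM2 0.40, DHODH 0.25, FECH 0.23 and PAX6 0.14, GC correction ACSL3 0.0375, AIFM2 0.0524, ATP5F1E 0.30, CCNG1 0.14, CXCL8 0.86, FECH 0.59, HSPA9 0.56, ITGB1 0.47, NCOA4 0.0248, NFE2L2 0.0895, PAX6 0.0410, SDHD 0.0184, SLC7A11 0.84 and UQCRB 0.0316, and GC and length correction ACSL3 0.11, AIFM2 0.0618, ATP5F1E 0.35, CCNG1 0.14, CXCL8 0.82, FECH 0.68, GCLM 0.0313, HSPA9 0.62, ITGB1 0.52, NCOA4 0.0150, NFE2L2 0.0900 and SLC7A11 0.95. The cause was not tested, beyond what each alternative does by construction. Of 2943 values of named genes under alternatives, 2865 kept direction and side of the threshold, 37 lost and 5 gained a call, and 36 turned. For lists these were 827, 50, 30 and 25 of 978, and 46 changed direction without being called on either side. Depth is unknown in TPM, so its limit on low genes cannot be given.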

Other observations

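All tests in this part were chosen only after the results were seen, except the splits of the libraries and the test of transcript length. Of 9 gene families chosen after seeing the data and adjusted over the 9, camera called 8 at the preset correlation and 0 with an estimated correlation. Some family members are also on the fixed lists, such as SARS1 and WARS1 among ATF4 targets and S100A4 among mesenchymal genes. Those family results are thus not separate from the lists. Metallothioneins, small proteins that bind zinc and copper, were lower, as none of 6 tested rose and 5 fell, scaled 0 and 5, GC-corrected 0 and 5 (camera adjusted p = 0.0370, adjusted p = 0.203 with an estimated correlation, 0.00318 after GC correction). MT2A fell from 6979.8 ± 188 to 3955 ± 38.3 TPM (SD, n = 3), with similar family members that can share its reads. Nucleoporins were lower, as 1 of 23 tested rose and 21 fell, scaled 2 and 16, GC-corrected 2 and 16 (camera adjusted p = 0.00569, adjusted p = 0.0997 with an estimated correlation, 0.00182 after GC correction), with NUP205 at −1.09 (GC-corrected −0.36). Of S100 calcium-binding proteins, 5 of 13 tested rose and 4 fell, scaled 11 and 1, GC-corrected 9 and 1 (camera adjusted p = 0.00237, adjusted p = 0.0997 with an estimated correlation, 0.00328 after GC correction), where S100P rose by 2.34 and S100A4 fell by 0.58 (scaled −0.02, not called). For cytosolic aminoacyl-tRNA synthetases, 8 of 18 tested rose and 9 fell, scaled 12 and 4, GC-corrected 11 and 2 (camera adjusted p = 0.0285, adjusted p = 0.147 with an estimated correlation, 0.00318 after GC correction), with SARS1 up by 0.93 and RARS1 at −1.08 (GC-corrected −0.07, not called). Among host genes of small nucleolar RNAs, 8 of 25 tested rose and 14 fell, scaled 14 and 5, GC-corrected 14 and 6 (camera adjusted p = 0.0285, adjusted p = 0.299 with an estimated correlation, 0.0311 after GC correction).

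Other families had camera calls that ended after GC correction. Of zinc finger genes named ZNF, 14 of 406 tested rose and 306 fell, scaled 57 and 192, GC-corrected 61 and 102 (camera adjusted p = 0.0285, adjusted p = 0.0997 with an estimated correlation, 0.150 after GC correction). Among hnRNP genes, which bind nuclear RNA, none of 28 tested rose and 26 fell, scaled 6 and 15, GC-corrected 8 and 11 (camera adjusted p = 0.00237, adjusted p = 0.213 with an estimated correlation, 0.269 after GC correction), and of the CCT chaperonin none of 10 tested rose and 10 fell, scaled 3 and 5, GC-corrected 4 and 2 (camera adjusted p = 0.0285, adjusted p = 0.203 with an estimated correlation, 0.324 after GC correction, there upward). Proteasome genes had no call (2 of 43 tested rose and 28 fell, scaled 19 and 13, GC-corrected 18 and 10, camera adjusted p = 0.0674). Median log2 fold changes as deposited and after GC correction were −0.73 and −0.06 for ZNF genes, −0.81 and −0.22 for hnRNP genes and −0.76 and 0.08 for CCT genes.

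Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. The real split gave 10202 changed genes, and the highest of the other splits gave 2. For changes of at least 2-fold these were 3194 and 2, for lists 19 and 13, and for terms 98 and 27. In each case 1 split, the real one, gave a result as large. Every other split mixes libraries of both groups, so the group difference enters its spread and few genes can be called. Such a split also keeps part of that difference, so its lists and terms do not show what no effect would give.

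The rise of fold changes with transcript GC content spanned 1.38 on the log2 scale (95% bootstrap interval 1.32 to 1.43) between the 10% of genes with the lowest and the highest GC content. Transcript length is argued against as the whole source, since the lowest rank correlation with GC content in any length bin was 0.406, although fold changes also went down with length (rho −0.291, and −0.149 after GC correction), which leaves a part of length open. A larger share for the top 100 genes is argued against as well, as it would lower all other genes alike by 0.185 without spreading them. A recovery of GC-rich fragments that differed between the groups' libraries may account for it, and the largest slope between libraries of 1 group was 0.00750 log2 per GC percent against 0.0445 to 0.0568 between groups. Since every library of a group shares its slope, this cannot be told apart from a change in the cells that follows GC content, such as one in RNA stability, which was not tested.

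The fall of mitosis and replication genes may be a real slowing of division in shCLPX-1 cells, a hypothesis found and examined on the same data. The GC trend is argued against as its whole source, since the GC-corrected medians stayed at −0.65 for mitosis (95% interval −0.93 to −0.41) and −0.58 for replication (−0.79 to −0.36), and at −0.34 (−0.46 to −0.15) for the 14 mitosis members of higher GC content. Both lists were still placed below other genes after GC and length correction (camera adjusted p = 2.16e-11 and 2.63e-06). Part of the size stays open, because fold changes also went down with transcript length across all genes. The corrected fold changes of mitosis members also still rose with GC content (rho 0.769 across genes, median −1.02 for the members of lower GC content). Cell counts or a cell cycle measurement, which are not in these data, would test it.

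Whether the rise of integrated stress response targets follows from loss of ClpX or from an off-target effect was not tested, and needs another hairpin or a rescue with CLPX. The GC trend is argued against, since the median stayed above 0 at 1.39 after the correction (95% interval 1.12 to 1.56). Handling at harvest that differed between the groups stays open and cannot be told apart from the hairpin, as immediate early genes rose as well and nothing is recorded of handling beyond freezing of the cells. Libraries of 1 group differed by at most 0.117 in the list's median log2(TPM + 1), which was 6.46 to 6.58 in shNS and 7.89 to 8.001 in shCLPX-1.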
